A study of Mus musculus with 10 samples.

How the data were processed

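Poly-A selected, stranded RNA libraries were aligned with STAR 2.5.1 to the mouse genome build mm10, and later steps used R 3.3.0, per the submitters' processing notes. The counting tool, the gene annotation and the kind of scaling between libraries were not given in the sources used here. The authors deposited 1 table of log2(CPM + 1) values with 11617 gene symbols and 10 libraries, and no gene had a value of 0 in any library. Back-transformed with 1 factor per library, 100% of the values of each library were whole read counts to within 0.1 read. The recovered factors correspond to 1 scaled library size each, and reads in the listed genes were 27398791 to 37559810 per library. The CPM of the listed genes summed to 959639 and 960837 in the control libraries and to 998260 to 1037796 in the treated ones. The scaled size is therefore not the plain number of reads. The lowest count of any listed gene was 3 reads, and each listed gene reached at least 1.085 CPM in some library. Genes without reads in some library are thus absent from the table, including any that are silent in control and induced by a ligand. Of 18 listed cytokines 15 were among the genes tested, and of 21 chemokines 16. List counts cover these members alone, which are called measured.

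Genes with a mean of at least 1 CPM over all libraries were tested, 11407 in number. A linear model with 1 mean per group was fitted to the deposited log2 values with limma 3.58.1 in R 4.3.3, with an intensity trend in the empirical Bayes step. The residual degrees of freedom were 5 and the prior degrees of freedom 14.7. There were 9 contrasts: each treated group against control, the ligands against each other at 1 h and at 3 h, 3 h against 1 h for each ligand, and the difference of the latter changes. P-values were adjusted by Benjamini-Hochberg within each contrast, and an adjusted p below 0.05 counted as a change. SE is the moderated standard error of the log2 fold change, and ± after a CPM value gives the standard deviation over the 2 libraries of a group. The SE uses 1 spread per gene shared by the 5 groups, so it may be too small for a group whose libraries differ more. Elsewhere the meaning of ± is given with the value. On the log2(CPM + 1) scale the change of genes of low level is understated.

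In all, 30 gene lists were written from textbook knowledge, and 29 had enough measured members. They were tested with camera in limma with a preset inter-gene correlation of 0.01, and again with a correlation estimated from the data as deposited; after the length and GC correction the preset value alone was used. For each list the members that changed were counted over all genes tested and with adjustment over the list alone. Some genes belong to more than 1 list and count in each. Transcript length, GC content and positions came from GENCODE M21, with 11366 tested genes matched. For the length and GC correction, each library's log2 values were taken relative to each gene's mean over libraries, were fitted against natural splines of log2 length and of GC content (5 degrees of freedom each), and the fitted trend was removed. To show what shared controls give, 100 simulations of unchanged groups were run with the measured spread of each gene. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

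Genes were named by a fixed rule. For each comparison of 2 groups it took the 8 largest rises and 8 largest falls in log2 fold among genes that changed. These needed a mean of 5 CPM in the higher group and each library of a group above each library of the other, and symbols beginning with Gm or ending with Rik were left out. Always named were Il10, Tnf, Il6, Il1b, Il12b, Ifnb1, Cxcl10, Tlr2, Arg1, Mrc1, Nos2 and Crem. From each list the 3 members with the largest change, or the 1 largest where none passed, could be named. The groups, comparisons, lists, threshold, naming rule and most alternatives were chosen before the data were examined. Among these alternatives were other filters, pseudocounts of 0.25 and 5, quantile and median scaling, other spread estimates, a term for the replicate number and leaving out each library. The length and GC correction, the fit on matched genes without it, and voom on the recovered reads were added after seeing the data.

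The calculation was tested on simulated data with the measured gene means and depths, for AmTARS at 1 h against control. Unlike in the data, each simulated gene had the same spread between libraries, and no length trend was added at first. It recovered 54% of genes changed 1.25-fold, 90% of those changed 1.5-fold and 100% of those changed 2-fold or 4-fold, with 6 false calls among 176. With a simulated length trend, 4052 unchanged genes were called before the correction and 9 after it, while 50 of 50 changed genes were called in both cases. That trend was linear in log2 length, a form that the correction can remove by its construction. With voom on the recovered reads, limma called 4425 genes for AmTARS and 5424 for Pam3CSK4 at 1 h against control. It called 4263 and 5651 at 3 h, and 21 and 2000 between the ligands at 1 h and 3 h.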

Results

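Messenger RNA was sequenced from bone-marrow-derived macrophages of C57BL/6 mice, grown with 10% fetal bovine serum and 50 ng/ml GM-CSF, a growth factor of myeloid cells. The cells were left untreated or received AmTARS or Pam3CSK4 for 1 h or 3 h. The name AmTARS reads as the threonyl-tRNA synthetase of the gut bacterium Akkermansia muciniphila, an enzyme that loads threonine onto its tRNA. Pam3CSK4 is a synthetic triacylated lipopeptide that activates Toll-like receptor TLR2 paired with TLR1. The series record gives its purpose as comparing mRNA levels under both ligands of TLR2. The 5 groups held 2 libraries each (n = 2 per group), and the control group carried no time label. Pam3CSK4 was given at 10 ng/ml, while the labels write the AmTARS dose as 0.5 with the unit mm, so the relation between the doses is unknown. The labels do not say that the 2 libraries of a group came from separate cultures or animals, so the p-values may measure technical spread alone. Reads in the listed genes ranged from 27398791 to 37559810 per library, and the 2 libraries of each group correlated at 0.998 across genes. Of 11617 listed genes, 11407 reached a mean of 1 CPM (counts per 1e6 of the scaled library size) and were tested.

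In each treated group, short transcripts were higher and long transcripts lower than in the control libraries. Across genes, which are not independent replicates, Spearman's rho between transcript length and log2 fold change was -0.73 for AmTARS at 1 h and -0.661 at 3 h. It was -0.729 for Pam3CSK4 at 1 h and -0.506 at 3 h. Between the ligands, rho was 0.346 at 1 h and -0.005 at 3 h. Each comparison was therefore also computed after each library was corrected for transcript length and GC content, a setting added after seeing the data.

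**Figure D1:**
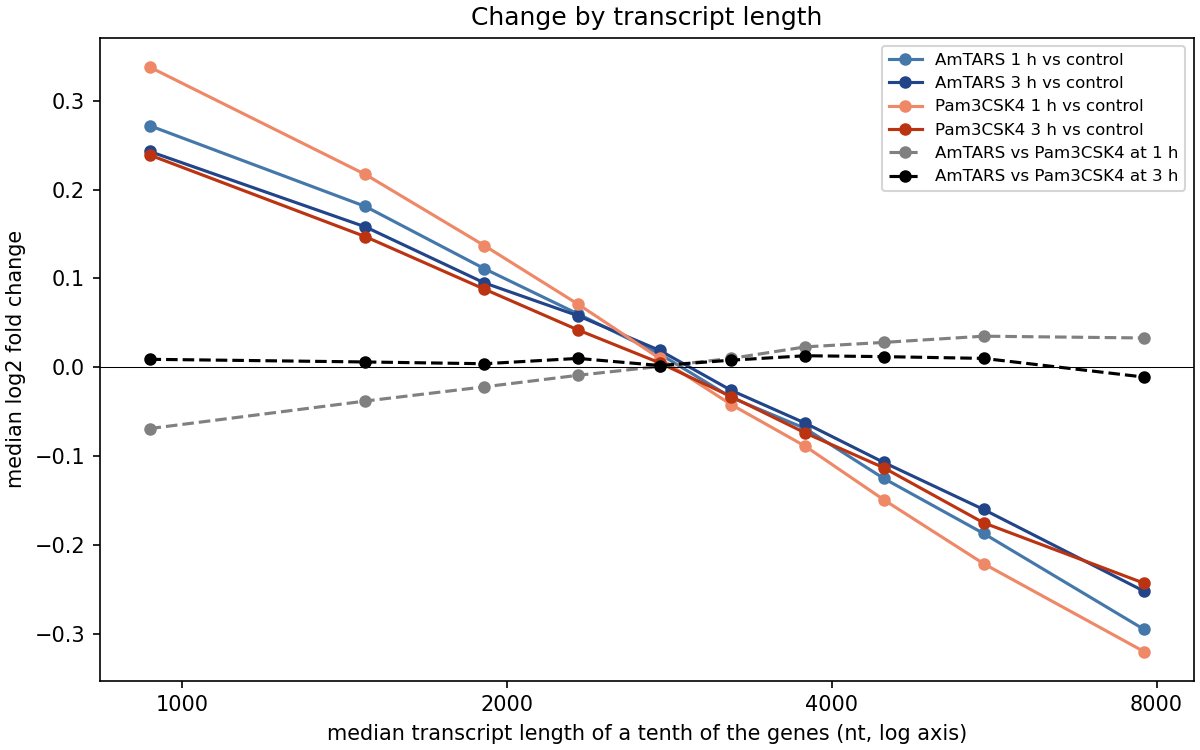
Median log2 fold change (vertical axis) against the median transcript length in nucleotides (horizontal, log axis) for 10 groups of genes of equal number, by comparison. With AmTARS at 1 h the tenth of genes with the shortest transcripts (median 933 nt) had a median of 0.27 and the tenth with the longest (7788 nt) a median of -0.29.

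AmTARS for 1 h changed single genes of cytokines, chemokines and their regulators relative to untreated cells. Tnf, the gene of tumour necrosis factor (chromosome 17, 35199381 to 35202007, genome build mm10), rose from 23.6 ± 0.0602 to 67.9 ± 5.47 CPM (SD, n = 2 per group), a log2 fold change of 1.48 (SE 0.07). Cxcl2 and Cxcl1, genes of chemokines that attract neutrophils, rose by 1.34 (SE 0.11) and 0.83 (SE 0.11) on the log2 scale. Il1b, the gene of interleukin-1 beta, rose by 0.93 (SE 0.13). Nfkbia and Nfkbiz, feedback regulators of the transcription factor NF-kB, rose by 0.84 and 0.78, Junb by 0.82 and Mir6236 by 1.10. Txnip, which encodes a regulator of glucose uptake, fell by 0.98 (SE 0.04), from 458 ± 7.67 to 231 ± 1.34 CPM. Zbed6 fell by 1.20, Cbl, a ubiquitin ligase gene, fell by 1.09, and Uhmk1, Pdpr, Clcn5, Uprt and Xrn1 fell by 0.95 to 1.04. For these 16 genes, both libraries of either group lay on the same side of both libraries of the other, and adjusted p in limma ran from 6.9e-12 to 4.27e-05. The values are as deposited. Falls of at least 2-fold numbered 6 as deposited and 1 after the length and GC correction, and rises 3 and 2. Part of the named falls and rises may thus follow the length trend.

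Among the gene lists fixed beforehand, 10 of 16 immediate-early genes rose with AmTARS at 1 h and 6 did not pass, with Dusp1 at 0.59 (SE 0.09) and Nr4a1 at 0.57 (SE 0.10). The camera test gave an adjusted p of 5.54e-05 for this list, and adjusted p = 0.683 with an estimated correlation. Of 20 NF-kB targets and feedback genes, 10 rose and 1 fell, Rel at -0.59 (adjusted p = 0.00283, and adjusted p = 0.842 with an estimated correlation). Of 16 chemokines, 10 rose, or 11 adjusted over the list alone, with Ccl4 at 0.47 (adjusted p = 0.000476, and adjusted p = 0.842 with an estimated correlation). After the length and GC correction, 8 immediate-early genes, 9 NF-kB genes and 4 chemokines rose. Of 21 genes of oxidative phosphorylation 16 rose, with Ndufa2 at 0.56. Their adjusted p was 7.3e-06, adjusted p = 0.842 with an estimated correlation, and 1 of the 21 rose after the correction. Of 12 genes of MHC class II and co-stimulation, 7 rose, or 8 adjusted over the list alone, and 1 fell (adjusted p = 0.015, and adjusted p = 0.842 with an estimated correlation). After the correction 2 of these 12 rose, and the list had an adjusted p of 0.337. With AmTARS at 1 h, 5 lists passed camera as deposited and 5 after the correction. Only 3 passed both times in the same direction, so other lists were gained. Of 15 inflammatory cytokines 4 rose and 1 fell, and the list did not pass (adjusted p = 0.111).

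Of the genes fixed by name, Cxcl10 rose by 0.43, Tlr2 rose by 0.17, Mrc1 fell by 0.27 and Nos2 fell by 0.26 with AmTARS at 1 h. After the correction Cxcl10 stood at 0.24 (adjusted p = 0.22), Mrc1 at -0.07 (adjusted p = 0.319) and Nos2 at -0.27 (adjusted p = 0.0605), so these 3 no longer passed. Il6 stood at 0.20, Il12b at -0.06, Arg1 at 0.09 and Crem at 0.18, and none of these passed. By limma with Benjamini-Hochberg adjustment 4415 genes changed, 2157 higher and 2258 lower, with a median size of 0.27 on the log2 scale. At least 2-fold changes were seen for 3 higher and 6 lower genes, and for 2 and 1 after the length and GC correction. The higher genes had a median transcript length of 1505.5 nt and the lower ones of 5463 nt. After the correction 1608 genes changed, 920 higher and 688 lower, of which 1125 had also changed in the same direction before it. Without control replicate 2 the count was 2606 genes.

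AmTARS for 3 h gave its largest rises in the chemokine gene Cxcl2, in Marcksl1 and in Wnt6. Cxcl2 rose by 1.36 (SE 0.11), Tnf by 1.02 (SE 0.07), from 23.6 ± 0.0602 to 49.1 ± 0.105 CPM, and Il1b by 0.94 (SE 0.13). Cxcl10, the gene of a chemokine that attracts T cells, rose by 1.02 (SE 0.14). Marcksl1 rose by 1.07, Wnt6, a gene of a secreted signalling protein, by 1.02, Gpr84, a receptor gene, by 0.97 and Cdc42ep2 by 0.92. Slc5a3, a gene of an inositol transporter, fell by 1.00, Zbed6 fell by 1.03, and Uprt, Xylt1, Lmbrd2, Pdpr, Lnpep and Mgat5 fell by 0.79 to 0.99. Adjusted p in limma ran from 2.56e-08 to 0.000113 for these 16 genes, each with the libraries of both groups apart. The values are as deposited. Rises of at least 2-fold numbered 5 as deposited and 2 after the correction, and falls 2 and 1. Part of the named rises and falls may thus follow the length trend. Tlr2, the gene of the receptor itself (chromosome 3, 83836272 to 83841767), rose by 0.56 (SE 0.06), from 247 ± 2.77 to 365 ± 0.626 CPM.

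Of the 20 NF-kB targets and feedback genes, 17 rose with AmTARS at 3 h, 1 fell and 2 did not pass, with Sod2 at 0.84, Nfkbie at 0.79 and Tnip3 at 0.71. The list's adjusted p was 6.45e-11, and adjusted p = 0.369 with an estimated correlation, and after the correction 17 rose and 1 fell. Of 17 genes of cholesterol synthesis and efflux 14 rose and 1 fell, with Fdps at 0.80 (SE 0.05), Fdft1 at 0.65 (SE 0.06) and Sqle at 0.62 (SE 0.05), all enzymes of the synthesis. The adjusted p was 7.43e-09, adjusted p = 0.132 with an estimated correlation, and 15 rose after the correction. Of 10 NRF2 targets 8 rose, such as Hmox1, which encodes the haem-degrading enzyme, at 0.45 (adjusted p = 0.000132, and adjusted p = 0.465 with an estimated correlation). Of 14 M1 macrophage markers 9 rose, or 10 adjusted over the list alone, and 1 fell, with Cd40 and Fpr2 at 0.65 each (adjusted p = 0.000144, and adjusted p = 0.465 with an estimated correlation). Of 16 immediate-early genes 10 rose and 1 fell (adjusted p = 0.000132, and adjusted p = 0.369 with an estimated correlation). Of 16 chemokines 8 rose, or 10 adjusted over the list alone, and 1 fell (adjusted p = 8.37e-05, and adjusted p = 0.465 with an estimated correlation).

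With AmTARS at 3 h, 8 of 12 ATF4 stress response genes rose, or adjusted over the list alone 9 with 1 lower (adjusted p = 0.00536, and adjusted p = 0.369 with an estimated correlation). Of 9 inflammasome genes 5 rose (adjusted p = 0.0483, and adjusted p = 0.465 with an estimated correlation). Of 15 cytokines 6 rose, 7 adjusted over the list alone, and 2 fell (adjusted p = 0.0295, and adjusted p = 0.574 with an estimated correlation), and 5 rose and none fell after the correction (adjusted p = 0.0548). The oxidative phosphorylation list rose in 15 of 21 members, 16 adjusted over the list alone (adjusted p = 2.2e-05, and adjusted p = 0.465 with an estimated correlation), and in 1 after the correction (adjusted p = 0.458). The MHC class II list rose in 8 of 12 members and fell in 1 (adjusted p = 0.00226, and adjusted p = 0.465 with an estimated correlation), and after it 4 rose and 1 fell (adjusted p = 0.0761). Of 23 interferon response genes 7 rose and 3 fell, and of 12 M2 macrophage markers 3 rose and 2 fell, with adjusted p of 0.312 and 0.908. Arg1 rose by 0.31 and Mrc1 fell by 0.24, but after the correction Arg1 stood at 0.19 (adjusted p = 0.0662) and Mrc1 at -0.07 (adjusted p = 0.301). Il6 stood at 0.41 (adjusted p = 0.065), Nos2 at 0.13, Il12b at -0.11 and Crem at 0.06 without passing. In all, 4186 genes changed, 2147 higher (median length 1605 nt) and 2039 lower (5257 nt), 5 and 2 of them at least 2-fold. After the correction 2106 changed, 1227 higher and 879 lower, 2 and 1 of them at least 2-fold. The count was 2313 without control replicate 2 and 2000 without AmTARS 3 h replicate 1.

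Pam3CSK4 for 1 h gave its largest rises in the chemokine genes Cxcl2 and Cxcl1 and the cytokine gene Tnf. Cxcl2 (chromosome 5, 90903871 to 90905938) rose from 17.8 ± 1.49 to 128 ± 0.664 CPM (SD, n = 2 per group), a log2 fold change of 2.79 (SE 0.11). Tnf rose by 2.75 (SE 0.07) to 165 ± 0.0782 CPM and Cxcl1 by 2.05 (SE 0.11). Tnfsf9, the gene of the ligand 4-1BBL, rose by 1.54, Egr1, an immediate-early transcription factor gene, by 1.52, and Nfkbiz by 1.44. Socs3, a feedback inhibitor of cytokine signalling, rose by 1.40 and Zfp36, which encodes a protein that destabilises cytokine mRNAs, by 1.33 (SE 0.05). Cbl, Zbed6, Uprt, Lmbrd2, Uhmk1, Hivep3, Pdpr and Mgat5 fell by 1.15 to 1.34. In limma, adjusted p ran from 5.38e-16 to 4.06e-06 for these 16 genes, each with the libraries of both groups apart. The values are as deposited. Falls of at least 2-fold numbered 21 as deposited and 4 after the correction, and rises 15 and 11. Part of the named falls and rises may thus follow the length trend. Il1b rose by 1.33, Cxcl10 by 0.97 and Tlr2 by 0.24. Mrc1 fell by 0.36, and after the correction stood at -0.11 (adjusted p = 0.0595). Il6 stood at 0.35, Il12b at 0.05, Arg1 at -0.04, Nos2 at -0.04 and Crem at 0.11 without passing.

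Of 16 immediate-early genes, 11 rose with Pam3CSK4 at 1 h, 12 adjusted over the list alone, with a median of 0.59 (adjusted p = 1.74e-07, and adjusted p = 0.285 with an estimated correlation). Of 16 chemokines 12 rose, 13 adjusted over the list alone (adjusted p = 6.05e-06, and adjusted p = 0.715 with an estimated correlation), and 8 rose after the correction. Of 20 NF-kB genes 10 rose and 2 fell (adjusted p = 0.000899, and adjusted p = 0.715 with an estimated correlation). Of 15 cytokines 5 rose, such as Osm at 0.88 (adjusted p = 0.00804, and adjusted p = 0.715 with an estimated correlation). Of 20 TLR2 pathway components 11 fell, 12 adjusted over the list alone, and 3 rose, with Tlr9 at -0.92 and Cd14, a co-receptor gene, at 0.54 (adjusted p = 0.0298, and adjusted p = 0.715 with an estimated correlation). After the correction 5 of these 20 fell and 2 rose, and the list had an adjusted p of 0.499. Of 21 oxidative phosphorylation genes 15 rose (adjusted p = 6.05e-06, and adjusted p = 0.715 with an estimated correlation), and 2 rose and 1 fell after the correction (adjusted p = 0.296). Of 12 MHC class II genes 7 rose and 1 fell (adjusted p = 0.0138, and adjusted p = 0.715 with an estimated correlation), and 5 rose after it (adjusted p = 0.202). In all, 5556 genes changed, 2730 higher (median length 1577 nt) and 2826 lower (5030 nt), 15 and 21 of them at least 2-fold. After the correction 2583 changed, 1317 higher and 1266 lower, 11 and 4 of them at least 2-fold.

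Pam3CSK4 for 3 h gave the largest changes of the series. The 2 libraries of this group also differed most. Their chi-square per degree of freedom against counting noise was 7.5, against 3.58 to 4.63 in the other groups. Since limma used 1 spread per gene for all 5 groups, SE and adjusted p may be too small in comparisons with this group. Cxcl2 rose to 311 ± 82.3 CPM, a log2 fold change of 4.03 (SE 0.11), and Cxcl1 by 3.77 and Cxcl3 by 3.43 (SE 0.11 each). Il1b (chromosome 2, 129364570 to 129371139) rose by 3.45 (SE 0.13), from 23.1 ± 2.23 to 269 ± 89.3 CPM, and Tnf by 3.07 (SE 0.07). Ptges, a gene of prostaglandin E synthesis, rose by 2.65, Marcksl1 by 2.76 and Gpr84 by 2.63. Rnf144b, a ubiquitin ligase gene, fell by 1.54, and Mtus1, Lrrc14b, Abcd2, Bmf, Gpr155, Lpar5 and Enc1 fell by 1.17 to 1.32. Adjusted p in limma ran from 6.38e-17 to 1.27e-07 for these 16 genes, each with the libraries of both groups apart. The values are as deposited, and falls of at least 2-fold numbered 26 as deposited and 16 after the correction. Nos2, the gene of inducible nitric oxide synthase (chromosome 11, 78920787 to 78960254), rose by 2.27 (SE 0.10), Il6 by 2.25 (SE 0.17), Cxcl10 by 2.22 (SE 0.14) and Tlr2 by 1.74 (SE 0.06). Il12b rose by 0.50, Arg1 by 0.42, Mrc1 fell by 0.34, and Crem stood at 0.13 without passing.

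Of 20 NF-kB targets and feedback genes 19 rose with Pam3CSK4 at 3 h, with a median of 1.34 (adjusted p = 2.02e-22, and adjusted p = 0.219 with an estimated correlation). All 14 M1 macrophage markers rose, with a median of 1.63 (adjusted p = 3.03e-13, and adjusted p = 0.219 with an estimated correlation). Of 16 chemokines 14 rose (adjusted p = 1.52e-14, and adjusted p = 0.219 with an estimated correlation). Of 15 cytokines 11 rose and 1 fell (adjusted p = 3.76e-08, and adjusted p = 0.219 with an estimated correlation). Of 15 genes of MAP kinase feedback 9 rose, with the phosphatase gene Dusp16 at 1.05 (adjusted p = 0.000186, and adjusted p = 0.219 with an estimated correlation). Of 10 NRF2 targets 8 rose, with the cystine transporter gene Slc7a11 at 1.65 and Txnrd1 at 0.88 (adjusted p = 1.9e-06, and adjusted p = 0.219 with an estimated correlation). Of 16 genes of glycolysis and HIF-1 10 rose and 1 fell, with the glucose transporter gene Slc2a1 at 1.16 and the lactate transporter gene Slc16a3 at 1.10 (adjusted p = 0.000186, and adjusted p = 0.462 with an estimated correlation). Of 17 cholesterol genes 12 rose and 2 fell, 13 and 3 adjusted over the list alone, with Abca1 at 0.58 and Abcg1 at -0.84, both genes of sterol efflux (adjusted p = 0.00762, and adjusted p = 0.219 with an estimated correlation). Of 9 inflammasome genes 6 rose, with Nlrp3 at 1.52 (adjusted p = 0.00066, and adjusted p = 0.219 with an estimated correlation). Of 16 immediate-early genes 9 rose, 10 adjusted over the list alone, and 1 fell, with Ier3 at 1.32 (adjusted p = 0.00193, and adjusted p = 0.219 with an estimated correlation).

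With Pam3CSK4 at 3 h, 8 of 12 ATF4 stress response genes rose and 1 fell (adjusted p = 0.00385, and adjusted p = 0.219 with an estimated correlation). Of 13 CREB targets 6 rose and 2 fell (adjusted p = 0.0431, and adjusted p = 0.466 with an estimated correlation). The MHC class II and oxidative phosphorylation lists rose in 8 of 12 and 17 of 21 members, with 1 of the 12 lower, and with adjusted p of 0.00762 and 0.00028, and 0.462 and 0.466 as adjusted p with an estimated correlation. After the correction 6 of these 12 and 1 of these 21 rose and 3 of the 12 fell, and both lists had an adjusted p above 0.05 (0.226 and 0.877). Of 20 TLR2 pathway components 6 rose and 3 fell, with Tlr1 at 0.90 and Cd14 at 1.58, and the list did not pass (adjusted p = 0.0941). After the correction 11 rose and 3 fell, and it passed (adjusted p = 0.000887), while as deposited adjusted p = 0.466 with an estimated correlation. Of 23 interferon response genes 4 rose, such as Gbp2 at 0.64, and 8 fell, such as Ifit2 at -0.51, with an adjusted p of 0.327. Of 15 anti-inflammatory mediators 8 rose, such as Irak3, a negative regulator of Toll-like receptor signalling, at 1.31, and 3 fell, or 4 adjusted over the list alone (adjusted p = 0.0542, adjusted p = 0.466 with an estimated correlation, and 0.011 after the correction). Of 12 M2 markers 4 rose and 2 fell, or 3 adjusted over the list alone (adjusted p = 0.785), and the median was -0.12 while the mean was 0.05. In all, 5576 genes changed, 2812 higher (median length 1952 nt) and 2764 lower (4547 nt), 127 and 26 of them at least 2-fold. After the correction 4766 changed, 2353 higher and 2413 lower, 132 and 16 of them at least 2-fold.

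**Figure D2:**
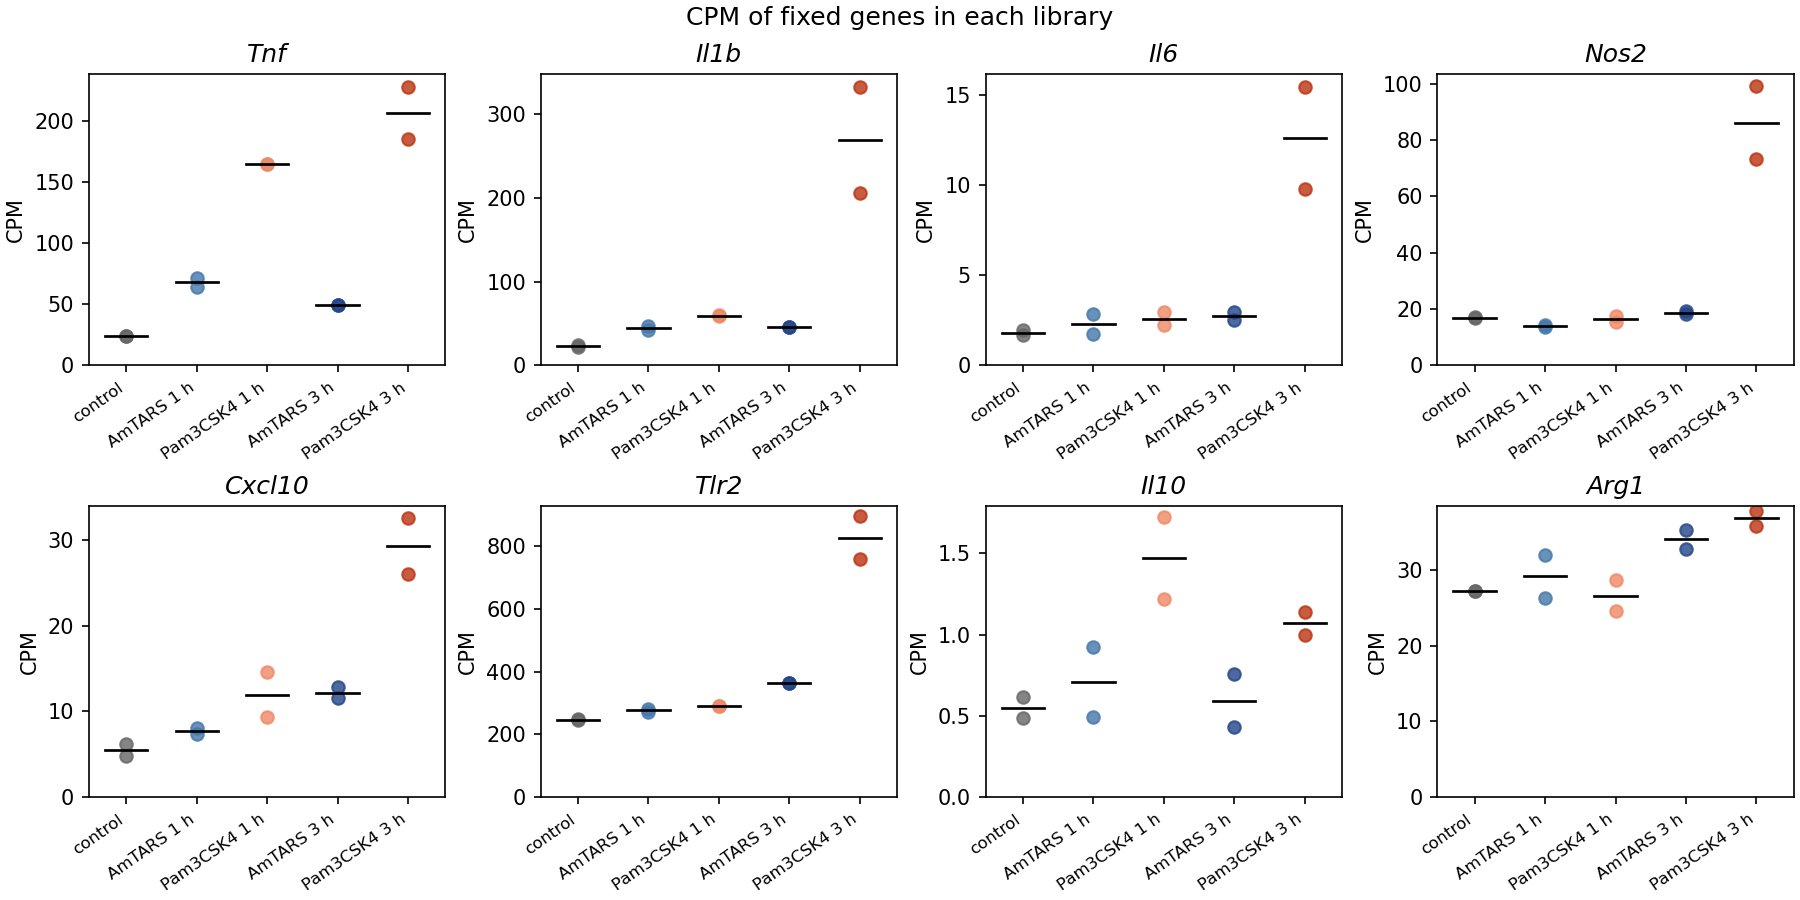
CPM (vertical axis, from 0) of 8 genes fixed by name in each of the 10 libraries, by group. Points are libraries and lines are group means; Tnf stood at 67.9 CPM with AmTARS and 165 with Pam3CSK4 at 1 h, and Il10 at 0.55 in control.

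AmTARS and Pam3CSK4 were compared directly at 1 h. Egr1 was lower with AmTARS by a log2 fold change of -1.37 (SE 0.09), at 7.48 ± 1.14 against 20.9 ± 1.05 CPM. Cxcl2 was lower by -1.45 (SE 0.11), Tnf by -1.27 (SE 0.07), Cxcl1 by -1.23 (SE 0.11) and Tnfsf9 by -1.03 (SE 0.09). Txnip (chromosome 3, 96557957 to 96561883) was lower by -0.86 (SE 0.04), Zfp36 by -0.80 and Socs3 by -0.77. Slc30a1, the gene of a zinc exporter, was higher with AmTARS by 0.35 (SE 0.06). In limma, adjusted p ran from 8.41e-11 to 0.0112 for these 9 genes. The immediate-early genes were lower in 6 of 16 members, and adjusted over the list alone in 9 with 1 higher. Their adjusted p was 2.17e-20, and adjusted p = 0.0325 with an estimated correlation, so this call held. The NF-kB list was lower in 4 of 20 members (adjusted p = 5.07e-05, and adjusted p = 0.598 with an estimated correlation). The chemokines were lower in 2 of 16, adjusted over the list alone in 4 (adjusted p = 7.35e-09, and adjusted p = 0.401 with an estimated correlation). The cytokines were lower in 1 of 15, adjusted over the list alone in 4 (adjusted p = 9.55e-07, and adjusted p = 0.401 with an estimated correlation). With the preset correlation 10 lists passed camera, 8 lower and 2 higher with AmTARS. Il1b stood at -0.40 (adjusted p = 0.371) and Cxcl10 at -0.55 (adjusted p = 0.211), and Il6, Il12b, Tlr2, Arg1, Mrc1, Nos2 and Crem did not pass either. In all, 21 genes differed, 1 higher and 20 lower with AmTARS, and 957 had an unadjusted p below 0.05. The count was 33 without Pam3CSK4 3 h replicate 2, 34 without replicate 3 of that group, and 42 with only the samples of the groups compared.

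After 3 h the ligands differed in many more genes. Cxcl1 was lower with AmTARS by -2.90 (SE 0.11), at 23.3 ± 1.13 against 184 ± 49.9 CPM. Cxcl2 was lower by -2.68, Cxcl3 by -2.57, Il1b by -2.51 (SE 0.13), Nos2 by -2.14 (SE 0.10) and Tnf by -2.05 (SE 0.07). Hcar2, a receptor gene for nicotinic acid, was lower by -1.89 and Ccl3, a chemokine gene, by -1.88. Rgs2, a regulator of G protein signalling (chromosome 1, 143999338 to 144004161), was higher with AmTARS by 1.14 (SE 0.07), at 118 ± 5.97 against 53.3 ± 6.14 CPM. Arrdc3 was higher by 1.11 (SE 0.07), Rnf144b by 1.10, Engase by 0.89, Mtus1 by 0.86, Bmf by 0.83 and Enc1 by 0.80. Scd2, a fatty acid desaturase gene, was higher by 0.85 (SE 0.05). Adjusted p in limma ran from 1.68e-13 to 2e-06 for these 16 genes, each with the libraries of both groups apart. Il6 was lower by -1.83, Cxcl10 by -1.20, Tlr2 by -1.18 and Il12b by -0.61. Arg1 stood at -0.11, Mrc1 at 0.10 and Crem at -0.07 without passing.

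All 20 NF-kB targets and feedback genes were lower with AmTARS than with Pam3CSK4 at 3 h, with a median of -0.80 (adjusted p = 6.71e-39, and adjusted p = 0.11 with an estimated correlation). Of 16 chemokines 14 were lower (adjusted p = 4.24e-22, and adjusted p = 0.11 with an estimated correlation). Of 15 cytokines 11 were lower, and adjusted over the list alone 1 was also higher (adjusted p = 2.06e-14, and adjusted p = 0.11 with an estimated correlation). Of 14 M1 markers 12 were lower (adjusted p = 4.04e-20, and adjusted p = 0.11 with an estimated correlation). Of 17 cholesterol genes 10 were higher with AmTARS, 12 adjusted over the list alone, and 1 was lower, with the synthesis enzymes Lss at 0.52 and Dhcr7 at 0.44 and the efflux gene Abca1 at -0.66. The adjusted p was 5e-06, and adjusted p = 0.11 with an estimated correlation. Of 23 interferon response genes 10 were higher, with Ifit3 at 0.48 and Ifit2 at 0.44, and 2 were lower, with Gbp2 at -0.50 (adjusted p = 0.00366, and adjusted p = 0.603 with an estimated correlation). Of 10 NRF2 targets 5 were lower, with Slc7a11 at -1.39 (adjusted p = 9.65e-06, and adjusted p = 0.252 with an estimated correlation). Of 16 glycolysis genes 6 were lower, 8 adjusted over the list alone (adjusted p = 6.86e-05, and adjusted p = 0.465 with an estimated correlation). Of 20 TLR2 pathway components 6 were lower, 7 adjusted over the list alone (adjusted p = 2.32e-06, and adjusted p = 0.11 with an estimated correlation).

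With AmTARS relative to Pam3CSK4 at 3 h, 8 of 15 MAP kinase feedback genes were lower and 1 higher (adjusted p = 2.78e-05, and adjusted p = 0.168 with an estimated correlation). Of 9 inflammasome genes 5 were lower and 1 higher (adjusted p = 4.6e-05, and adjusted p = 0.172 with an estimated correlation). In all, 1953 genes differed, 917 higher and 1036 lower with AmTARS, 3 and 79 of them at least 2-fold. The balance turned with quantile normalization (1062 higher, 892 lower) and after the length and GC correction (1263 and 1232). The count was 1193 without AmTARS 3 h replicate 1 and 1139 without Pam3CSK4 3 h replicate 3. All 127 genes that Pam3CSK4 raised at least 2-fold at 3 h were lower with AmTARS by the direct test, which shares the Pam3CSK4 libraries with the choice of genes. Chosen in 1 Pam3CSK4 library and compared in the other, 110 of 110 and 160 of 160 genes were lower in both AmTARS libraries. Of the 127 genes, 107 also rose with AmTARS relative to control, and the medians were 1.48 with Pam3CSK4 and 0.45 with AmTARS. At 1 h there were 15 such genes, 14 of which rose with AmTARS and 12 of which were lower than with Pam3CSK4 by the direct test. Of the 26 genes that Pam3CSK4 lowered at least 2-fold at 3 h, 19 fell less with AmTARS by the direct test. At 1 h Pam3CSK4 lowered 21 genes at least 2-fold. All 21 also fell with AmTARS and 0 differed by the direct test, with medians of -1.12 with Pam3CSK4 and -0.90 with AmTARS. After the length and GC correction Pam3CSK4 lowered 4 genes at least 2-fold at 1 h. Both ligands were also set against the same control libraries. The length trend and the shared controls may therefore account for part of these falls.

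**Figure D3:**
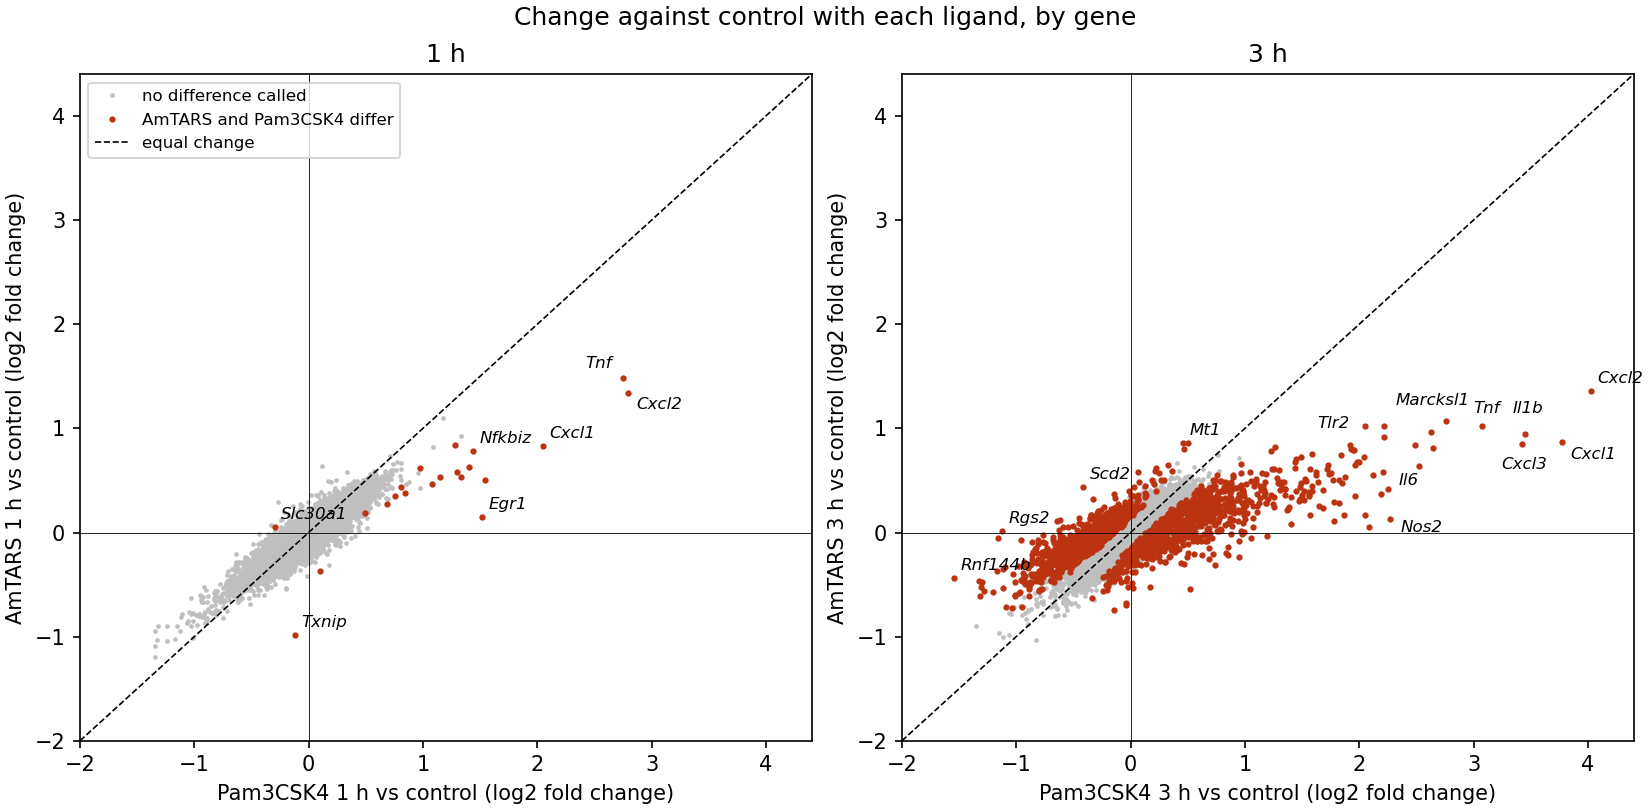
Log2 fold change against control with AmTARS (vertical axis) and with Pam3CSK4 (horizontal axis), 1 point per gene, at 1 h and 3 h; red points differ between the ligands by the direct test and the dashed line marks equal change. At 3 h the red points at the right lie far below the line, with Cxcl1 at 3.77 with Pam3CSK4 and lower with AmTARS by -2.90.

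The fold changes of both ligands against control correlated across genes at 0.93 (Pearson) at 1 h and 0.767 at 3 h. Unchanged groups simulated from noise alone, with 2 simulated control libraries shared by both, gave 0.499 and 0.502. The setup fixes these values by its construction. It held no length trend, so the gap does not measure a shared response to the ligands. The covariance was 0.0557 at 1 h against 0.00383 simulated, and 0.0558 at 3 h against 0.00386. At 1 h 2008 genes were higher with both ligands, against 516 for independent lists, 2059 were lower with both, against 559, and 0 moved in opposite directions. At 3 h 1778 were higher with both, against 529, 1582 lower with both, against 494, and 29 moved in opposite directions. Part of the excess may come from the shared control libraries and from the trend with transcript length. After the length and GC correction the correlations were 0.853 and 0.723 and the covariances 0.0233 and 0.0356. Higher with both ligands were then 819 genes at 1 h and 1030 at 3 h, and lower with both 589 and 738.

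Between 1 h and 3 h of AmTARS, the list of cholesterol genes and several single genes rose. Untreated cells formed 1 group without a time label. Changes between times with either ligand therefore cannot be told apart from time in culture. Irg1, whose product makes itaconate, rose by 0.84 (SE 0.08), from 179 ± 4.06 to 320 ± 16.5 CPM, and Acsl1, a gene of fatty acid activation, by 0.78 (SE 0.07). Wnt6 rose by 0.79, the receptor gene Fpr1 by 0.75, Irak3 by 0.70, Gpr84 by 0.69, Ptges by 0.68 and Egln3 by 0.68. Slc5a3 fell by 0.64, Tnf fell by 0.46 (SE 0.07), and Mir703, Hpgd, Cnn1, P2ry1, Zfyve28 and Lrrc14b fell by 0.47 to 0.60. In limma, adjusted p ran from 2.01e-06 to 0.0176 for these 16 genes. Cxcl10 rose by 0.60, Tlr2 by 0.40 and Nos2 by 0.39. Il1b stood at 0.02 (adjusted p = 0.982), and Il6, Il12b, Arg1, Mrc1 and Crem did not pass. The cholesterol list rose in 15 of 17 members and fell in 1, with Sqle at 0.58 and Lss at 0.49. Its adjusted p was 1.12e-29, and adjusted p = 0.00762 with an estimated correlation, so this call held. The median of the list rose between times with both ligands, by 0.399 with AmTARS and by 0.262 with Pam3CSK4. The NF-kB list rose in 11 of 20 members and fell in 1, or in 2 adjusted over the list alone (adjusted p = 1.23e-10, and adjusted p = 0.39 with an estimated correlation). The NRF2 list rose in 6 of 10, 9 adjusted over the list alone (adjusted p = 6.1e-13, and adjusted p = 0.242 with an estimated correlation). The interferon list rose in 1 of 23, Mx1 at 0.42, and adjusted over the list alone in 5 with 1 lower (adjusted p = 0.00155, and adjusted p = 0.641 with an estimated correlation). In all, 271 genes changed, 206 higher and 65 lower, and 456 after the correction. None changed at least 2-fold, and 1376 had an unadjusted p below 0.05. The count was 95 and 158 without AmTARS 1 h replicates 2 and 3, 147 and 89 without AmTARS 3 h replicates 1 and 3, and 63 without the trend of variance with level.

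Between 1 h and 3 h of Pam3CSK4, 10 of 15 inflammatory cytokines rose and 1 fell, or 11 and 1 adjusted over the list alone (adjusted p = 9.43e-07, and adjusted p = 0.275 with an estimated correlation). Cxcl3 rose by 2.89 (SE 0.11), from 35.2 ± 0.683 to 272 ± 75.3 CPM, Ptges by 2.42, Irg1 by 2.39, Gpr84 by 2.32, Nos2 by 2.30, Il1b by 2.12 and Ifi205 by 2.11. Rasgrp1 rose from 1.2 ± 0.24 to 11.5 ± 1.67 CPM. Egr1 (chromosome 18, 34859823 to 34864984) fell by 1.34 (SE 0.09), from 20.9 ± 1.05 to 7.62 ± 0.297 CPM, Rnf144b fell by 1.27, and Rgs2, Bmf, Engase, Abcd2, Fam214a and Lrrc14b fell by 1.07 to 1.19. Adjusted p in limma ran from 4.34e-14 to 1.23e-07 for these 16 genes. Tlr2 rose to 828 ± 96.3 CPM and Cxcl10 to 29.3 ± 4.64 CPM. Il6 rose by 1.90, Arg1 by 0.46, Il12b by 0.45 and Tnf by 0.32, while Mrc1 at 0.02 and Crem at 0.02 did not pass. Of 16 immediate-early genes 10 fell and 1 rose (adjusted p = 0.00032, and adjusted p = 0.216 with an estimated correlation). Of 20 NF-kB genes 19 rose, with Icam1, an adhesion receptor gene, at 1.49 (adjusted p = 2.46e-25, and adjusted p = 0.175 with an estimated correlation). Of 16 chemokines 14 rose (adjusted p = 4.52e-13, and adjusted p = 0.216 with an estimated correlation). Of 20 TLR2 pathway components 15 rose, 18 adjusted over the list alone, and 1 fell (adjusted p = 3.14e-08, and adjusted p = 0.175 with an estimated correlation). In all, 3597 genes changed, 1851 higher and 1746 lower, 128 and 11 of them at least 2-fold. The balance turned with quantile normalization (1576 higher, 2014 lower) and after the correction (1863 and 1915). The count was 2380 without Pam3CSK4 1 h replicate 1.

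The change from 1 h to 3 h itself differed between the ligands in 1049 genes by limma, 398 with a higher and 651 with a lower value for AmTARS minus Pam3CSK4. Of the 20 NF-kB genes 19 had a lower value (adjusted p = 1.32e-35, and adjusted p = 0.114 with an estimated correlation), with a median of -0.76. Of 16 chemokines 13 were lower (adjusted p = 1.05e-17, and adjusted p = 0.191 with an estimated correlation). Of 15 cytokines 10 were lower (adjusted p = 1.21e-10, and adjusted p = 0.191 with an estimated correlation). Of 16 immediate-early genes 6 had a higher value, and adjusted over the list alone 1 also a lower (adjusted p = 0.000233, and adjusted p = 0.191 with an estimated correlation). Of 17 cholesterol genes 8 had a higher value and 1 a lower, or 2 adjusted over the list alone (adjusted p = 0.00363, and adjusted p = 0.217 with an estimated correlation). The count was 676 without AmTARS 3 h replicate 1 and 680 without the trend of variance with level.

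**Figure D4:**
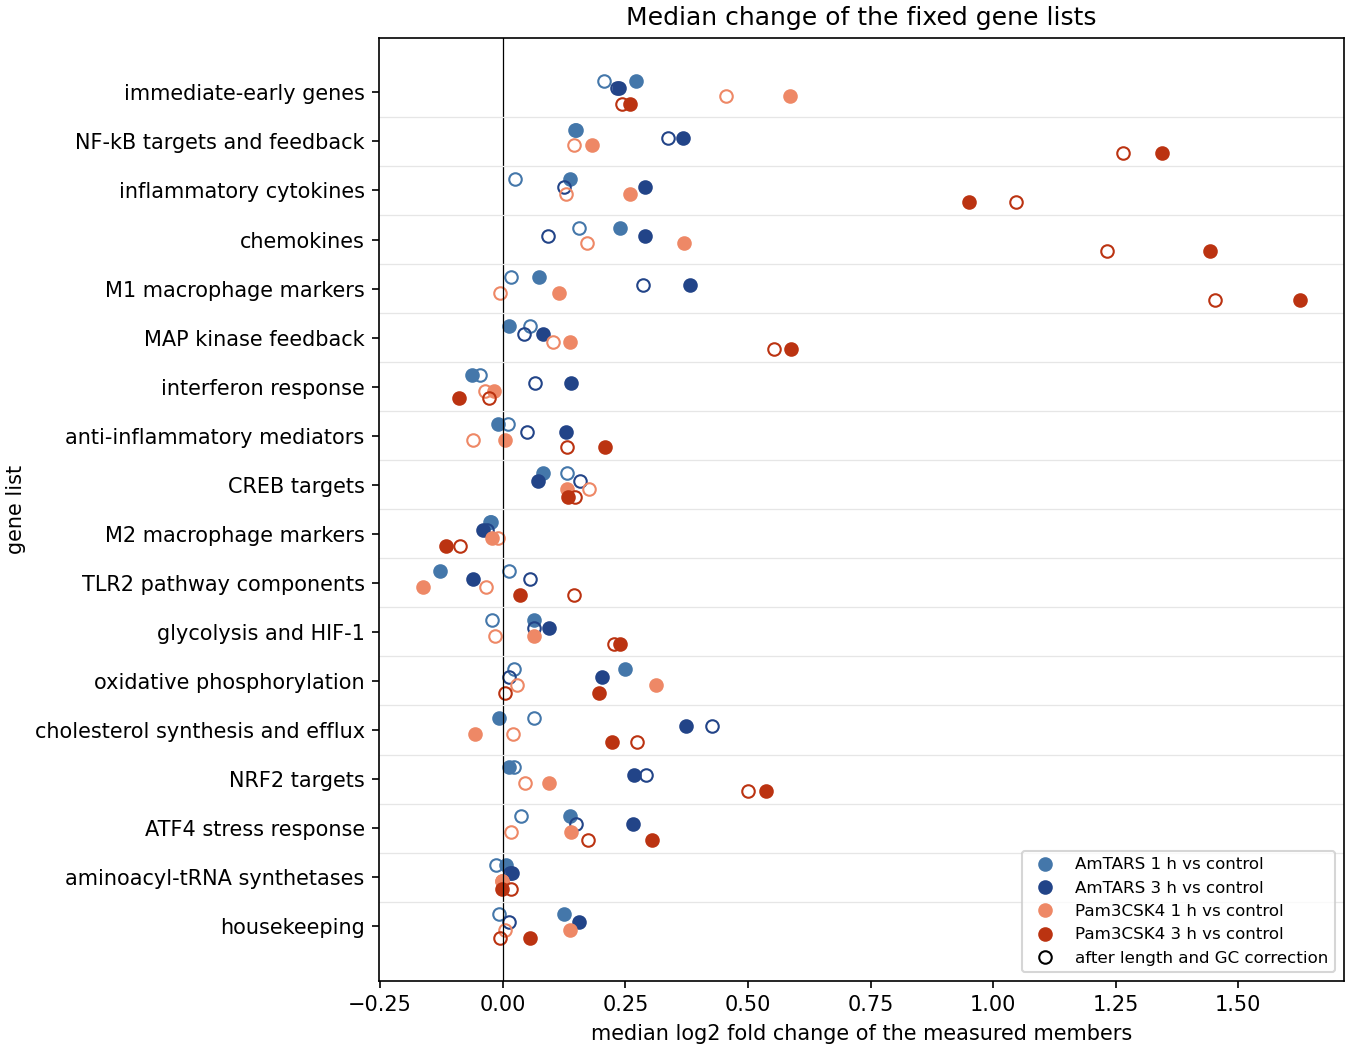
Median log2 fold change against control of the measured members of 18 gene lists (horizontal axis), by ligand and time; filled points are as deposited and open points after the length and GC correction. The NF-kB list lies at 1.34 with Pam3CSK4 at 3 h and at 0.37 with AmTARS at 3 h, and the oxidative phosphorylation list falls close to 0 after the correction.

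Il10, the gene of the anti-inflammatory cytokine interleukin-10, averaged 0.879 CPM over all libraries, below the level required for testing. It stood at 0.55 ± 0.091 CPM in control, 0.709 ± 0.302 and 0.592 ± 0.231 with AmTARS at 1 h and 3 h, and 1.48 ± 0.357 and 1.07 ± 0.0979 with Pam3CSK4 (SD, n = 2 per group). Without the filter, limma gave Il10 a log2 fold change of 0.67 with Pam3CSK4 at 1 h (adjusted p = 0.00159) and of 0.13 with AmTARS at 1 h (adjusted p = 0.542). The direct difference of the ligands in Il10 at 1 h was -0.54 (adjusted p = 0.286). At such levels the scale log2(CPM + 1) understates the change. Ifnb1, also fixed by name, was absent from the table and was not analysed here.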

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

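Chosen only after the result was seen were the slope test of the control libraries, the choice of genes in 1 library and comparison in the other, and the share of Pam3CSK4-raised genes still lower with AmTARS after the correction. A difference between groups drew attention to the genes below: limma tested whether the change from 1 h to 3 h differed between AmTARS and Pam3CSK4, which equals the change of their difference. It did so for 1049 genes. Among 29 genes looked at, the largest of both direct comparisons of the ligands and those fixed by name, 23 passed, 11 higher and 12 lower. Over all genes tested 9.2% passed. The largest ones were picked for an extreme difference at 1 h or 3 h in these same libraries. Passes among them therefore follow in part from the choice. With 2 libraries per group, which library of a pair deviates cannot be seen, and no count of other splits was made.

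The difference, AmTARS minus Pam3CSK4, fell between 1 h and 3 h for genes of inflammatory mediators. On the log2 scale its change was -2.44 for Cxcl3 (SE 0.15, adjusted p = 4.52e-09 in limma), -2.11 for Il1b, -1.91 for Nos2, -1.69 for Il6, -1.68 for Cxcl1, -1.60 for Ccl3, -1.57 for Hcar2 and -1.23 for Cxcl2. It was -1.11 for Tlr2, -0.84 for Socs3, -0.78 for Tnf and -0.65 for Cxcl10. It rose for Egr1 by 1.44, Rgs2 by 1.15, Rnf144b by 1.02, Arrdc3 by 0.98, Bmf by 0.91, Engase by 0.90 and Scd2 by 0.86. It rose as well for Txnip by 0.81, Enc1 by 0.79, Mtus1 by 0.78 and Zfp36 by 0.71. For Egr1 and Zfp36 this followed a fall with Pam3CSK4 after 1 h, and for Txnip a return after the fall with AmTARS.

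Many genes shifted by small amounts between treated and control libraries. With AmTARS at 1 h, 4402 genes were called before the length and GC correction and 1608 after it. The share was 0.365 ± 0.075, and 1125 genes were called in the same direction in both. Here ± is the standard deviation over fits with each library left out in turn. These fits share most libraries, so it is not a standard error. A length trend may account for many of these calls. Scaling is argued against, since quantile normalization gave 1.005 times as many calls (± 0.01 over the same kind of fits). Control libraries set apart by handling or batch and treatment cannot be told apart. Outside the lists the AmTARS shift was 0.805 ± 0.004 of the Pam3CSK4 shift at 1 h, near the bound of 0.8 for a common offset. It was 0.619 ± 0.047 for called NF-kB genes, which were kept for being called with either ligand at 1 h. For both slopes ± is a bootstrap spread over genes of the same libraries. It does not measure the spread between libraries, so the slopes cannot be held against the bound or each other. A biological change of short and long transcripts by both ligands stays open, untested.

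Mt1, Mt2 and Slc30a1, 3 metal-response genes, were higher with AmTARS than with Pam3CSK4 at 3 h, by a mean of 0.357 ± 0.035. In this paragraph ± is an SE that takes the 3 genes as independent. They are on no fixed list and were picked with their values in view. The mean is therefore no test of metal-response genes as a class. With AmTARS at 3 h against control, Slc30a1 stood at 0.147 (adjusted p = 0.0692 in limma). Metal ions brought with the AmTARS preparation were tested by the mean at 1 h, which was 0.034 ± 0.035 (0.088 ± 0.03 after the length and GC correction), against a bound of 0.2 for a rise of all 3. Its members went both ways: Mt1 stood at -0.10 and Mt2 at -0.15, while Slc30a1, the gene of a zinc exporter, was higher by 0.35 (adjusted p = 0.0112 in limma). The values argue against metal that raised all 3 genes within 1 h. Metal acting on Slc30a1 alone or after 1 h, and a difference in the response to either ligand, stay open and untested.

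Genes raised at least 2-fold by Pam3CSK4 at 3 h responded less to AmTARS, while others such as Mt1 and Mt2 did not. Endotoxin in the AmTARS preparation, acting through TLR4 and interferon, could be neither found nor excluded. The ratio of the AmTARS to the Pam3CSK4 effect at 3 h, interferon list minus NF-kB list, was -2.066 with an interquartile range of 1.833. The Pam3CSK4 mean of the interferon list, -0.043 (bootstrap SE over genes 0.057), lies near 0, so the ratio is unstable and the sources cannot be told apart. The AmTARS mean of that list was 0.076 (bootstrap SE over genes 0.038). The ratio is thus negative only through the Pam3CSK4 mean, and its sign tells nothing about endotoxin. In the direct comparison at 3 h the interferon list passed camera as higher with AmTARS, but not with an estimated correlation. After the length and GC correction 100% of the 127 genes remained lower. The same held when genes were chosen in 1 Pam3CSK4 library and compared in the other (104 of 104 and 160 of 160 genes). This outcome could hardly differ, since rho of the ligand difference at 3 h was -0.005 with length and 0.128 with GC content. The median difference of the 127 genes was -1.065 before the correction and -1.063 after it. The near absence of a length trend between the ligands, rather than this count, argues against transcript length. GC content was not tested apart. A lower effective dose of AmTARS stays open, since each ligand had a single dose.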

How the results depend on the processing

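The length and GC correction, its matched-gene fit and voom were added after seeing the data. Across 24 settings, the named genes gave 620 values of gene and comparison. Among values that had passed the threshold, the direction was reversed in 8, all under the length and GC correction. Values that had not passed changed sign 36 times, for 22 of them, such as Il12b with AmTARS at 1 h without control replicate 3 (0.23). Of the 620, 599 stayed on the same side of the threshold with quantile normalization, 612 with voom on the recovered reads, 573 with the replicate block, 544 with eBayes without trend, 532 with the length and GC correction and 219 with the added fold threshold.

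Under the length and GC correction the log2 fold change moved in sign, without passing the threshold, for Slc7a11 to 0.0466 and Mki67 to 0.0403 and B2m to -0.0077 with AmTARS at 1 h, and for Mki67 to 0.0028 with AmTARS at 3 h. With Pam3CSK4 it moved for Slc7a11 to 0.1051, Cenpe to 0.0096 and Prss34 to -0.0299 at 1 h, and for Col3a1 to 0.0027 at 3 h. The gene counts under the correction were 1608 and 2106 for AmTARS at 1 h and 3 h, 2583 for Pam3CSK4 at 1 h and 456 for AmTARS 3 h against 1 h. By its construction the correction removes the trend with length and GC content.

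With also an absolute log2 fold change of at least 1, counts were 9, 7, 36 and 153 against control (AmTARS 1 h and 3 h, Pam3CSK4 1 h and 3 h), 5 and 82 between the ligands at 1 h and 3 h, 0 and 139 between times (AmTARS, Pam3CSK4), and 68 for the difference of these changes. The threshold itself excludes smaller changes. For the count of 0, limma had 1376 genes at an unadjusted p below 0.05. With eBayes without trend, AmTARS 3 h against 1 h gave 63 genes and the difference of changes 680. With only the samples of the groups compared, the ligands at 1 h gave 42 and AmTARS 3 h against 1 h 492. The cause was not tested.

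The replicate numbers of the labels need not pair samples, and correlations across genes of the difference between the 2 libraries, for groups sharing both numbers, ranged from -0.179 to 0.204. With the replicate block AmTARS at 3 h against control gave 2017 genes and the difference of changes 672, and the cause was not tested. After the length and GC correction, 11, 7 and 15 lists passed for AmTARS at 3 h and Pam3CSK4 at 1 h and 3 h, as many as before it. Of these, 8, 4 and 13 passed both times in the same direction, so lists were both lost and gained. The gene list tests with an estimated correlation gave 0 lists in the 4 control comparisons, 1 and 0 between the ligands at 1 h and 3 h, 1 and 0 between times for AmTARS and Pam3CSK4, and 0 for the difference of changes. The cause was not tested.

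Leaving out each library in turn left an arm with 1 sample, assumed to vary like the other groups. Counts against control ranged from 2606 to 4702 and 2000 to 4437 for AmTARS at 1 h and 3 h, and from 3758 to 5798 and 3841 to 5629 for Pam3CSK4. They ranged from 15 to 34 and 1139 to 2098 between the ligands at 1 h and 3 h, from 89 to 381 and 2380 to 3493 between times for AmTARS and Pam3CSK4, and from 676 to 1330 for the difference. The correlation of the fold changes ranged from 0.892 to 0.938 at 1 h and from 0.729 to 0.785 at 3 h. Fewer libraries lower the power by construction, but the cause of single values was not tested. At this depth and number of libraries, 90% of simulated genes changed 1.5-fold were recovered, with the same spread for each gene and no length trend. Recovery in the data may differ.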

Other observations

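At 3 h, 88 genes rose with AmTARS against control and lay above Pam3CSK4 by the direct test, and 150 fell and lay below it, by limma. Of these genes, 40 and 37 also met both conditions after the length and GC correction. Genes that met them only after it were not counted. The genes of this paragraph and the next were chosen after their values were seen unless fixed by the naming rule. Among the higher ones were the sterol synthesis genes Lss, Sqle and Mvd and the single lipid genes Scd2 and Acsl3. Scd2 stood at 0.43 with AmTARS and -0.41 with Pam3CSK4 on the log2 scale, Acsl3 at 0.32 and -0.33, Lss at 0.37 and -0.15, and Sqle at 0.62 and 0.22. Mvd stood at 0.59 and 0.22. The metallothionein genes Mt1 and Mt2, whose products bind zinc and copper, stood at 0.86 each with AmTARS and at 0.46 and 0.50 with Pam3CSK4. After the correction Mt1 stood at 0.53 and 0.13 and Mt2 at 0.55 and 0.19. The antiviral genes Mx1 and Rsad2 stood at 0.28 and 0.24 with AmTARS and at -0.05 and -0.09 with Pam3CSK4. Among the lower ones, Inhba stood at -0.74 and -0.14, Klf7 at -0.69 and -0.04, and Ccl22 at -0.21 and 0.62. Ptgs2 stood at -0.23 and 0.95, and its AmTARS value was -0.09 (adjusted p = 0.493) after the correction. The correction moved other values by more than 1.5 times: Klf7 to -0.45 with AmTARS and 0.19 with Pam3CSK4, and with Pam3CSK4 Scd2 to -0.23, Lss to -0.01, Mvd to 0.04 and Inhba to 0.04. It also moved Mx1 to 0.00 and Rsad2 to -0.03 with Pam3CSK4.

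At 1 h only Txnip and Arrdc4, genes of related arrestin-like proteins, fell with AmTARS and lay below Pam3CSK4 by limma (2 genes). Txnip stood at -0.98 with AmTARS and -0.12 with Pam3CSK4, and at 3 h at -0.33 and -0.28. Arrdc4 stood at -0.37 and 0.10 at 1 h, and at -0.08 and 0.67 at 3 h. Both differences at 1 h passed after the correction, -0.87 for Txnip and -0.49 for Arrdc4.

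Several lists passed camera in none of the 9 comparisons as deposited; after the length and GC correction the stromal list was lower with AmTARS than with Pam3CSK4 at 1 h (adjusted p = 0.00752, and as deposited adjusted p = 0.598 with an estimated correlation), with 0 of 8 members called by limma and 957 of all genes at an unadjusted p below 0.05. For AmTARS at 3 h against control their adjusted p was 0.757 for 20 aminoacyl-tRNA synthetases (3 higher, 2 lower), 0.712 for 23 cell cycle genes (3 higher, 2 lower), 0.64 for 10 heat shock genes (1 lower) and 0.364 for 10 housekeeping genes (5 higher, 2 lower). For markers of other cells it was 0.279 for 2 measured dendritic cell genes (1 lower), 0.624 for 7 of mast cells and basophils (2 higher), 0.551 for 2 of B cells, 0.347 for 8 of stromal cells (1 higher, 1 lower) and 0.197 for 4 of red cells and platelets (2 higher). None of 10 T and NK cell markers was among the genes tested. As deposited, the 12 macrophage markers passed between the ligands at 1 h (adjusted p = 0.0335, and adjusted p = 0.401 with an estimated correlation), with 0 members called by limma. After the correction they also passed for Pam3CSK4 at 1 h against control, with 1 higher and 5 lower (adjusted p = 0.0334, and as deposited adjusted p = 0.995 with an estimated correlation). As deposited, the 11 neutrophil markers passed with Pam3CSK4 at 3 h, with 7 higher and 1 lower (adjusted p = 0.0184, and adjusted p = 0.427 with an estimated correlation). After the correction they also passed between the ligands at 3 h, with 1 higher and 4 lower with AmTARS (adjusted p = 0.0434, and as deposited adjusted p = 0.474 with an estimated correlation).

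The slope of each library's log2 values, relative to the gene means, on log2 transcript length was 0.146 and 0.120 in the control libraries. It was -0.0439 and -0.0253 with AmTARS at 1 h, -0.0323 and 0.0065 at 3 h, -0.0968 and -0.0399 with Pam3CSK4 at 1 h, and 0.006 and -0.04 at 3 h. The 10 most abundant genes took 22.3 to 24.1% of the reads. The spread between the 2 libraries of a group, as chi-square per degree of freedom against counting noise, was 3.58 in control and 7.5 with Pam3CSK4 at 3 h.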
